A study of Mus musculus with 6 samples.

How the data were processed

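RNA was measured by bulk sequencing in 6 libraries of mouse dermal fibroblasts, 3 labelled wild type (WT) and 3 labelled as lacking thrombospondin-2 (TSP2KO). Per the labels' protocols, the cells came from the dorsal skin of 12-week-old mice. The dermis was parted from the epidermis and fat after trypsin, digested with collagenase, and cultured for 3 to 5 days in medium with serum to enrich fibroblasts. RNA was taken at passage 1, and libraries were made with a kit that selects poly(A) RNA and keeps the strand. The labels do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical in part.

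The values deposited by the authors are a normalised signal per gene, listed under a name that describes them as normalised counts, for 23407 genes in 6 columns. Per the submitters' processing notes, the genome build was mm10, and STAR, Partek and DESeq2 were used, without role or order. The same notes name Cell Ranger and Seurat 5.0.3, tools for single cells, which were not analysed here. The counting options, the strand setting and the annotation release are not given in the sources used here. The coordinates of 96.4% of the genes were identical to those of GENCODE M21 after 1 base was taken off the stop, and coordinates are given here in that form, counted from 1, on mm10. The median ratio of each library to the geometric mean of all 6 lay between 0.997 and 1.02, as division by a size factor per library gives. Each library's low values fell on steps of a constant size, taken as the worth of 1 read. Between 67.1% and 72.6% of the values above 0 were whole multiples of that step within 0.02 of a read, and between 74.6% and 76.8% of the values of up to 200 reads. Whole reads were therefore not recovered, and the count tests planned for that case were not run. Dividing each total by the step gave an estimated depth of 14776468 to 34599724 reads per library. Columns were matched to samples by genotype and replicate number, since the library suffixes in the column names differ from those in the labels.

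Genes with a mean value of at least 10 over the 6 libraries were tested, 14707 in all. Values were taken as log2(value + 1), and TSP2KO was compared with WT by limma 3.58.1 in R 4.3.3, with a linear model per gene, a mean-variance trend and shrunken variances, two-sided. Fold changes are on that log2 scale, which understates the change of low genes. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. All 6 libraries stayed in the groups of their labels. Means and SDs are of the deposited values, while fold changes are differences of mean log2 values.

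Before the data were examined, 43 gene lists were fixed. They cover matrix and matrix turnover, fibroblast states, signalling pathways, immune genes, cell cycle, stress, metabolism and the markers of other cell types of skin. Of these, 42 were tested with camera of limma at its preset correlation between genes of 0.01, adjusted over the 42 lists. The remaining list, of sex-linked genes, served as a check of the samples. Members past the threshold were also counted with p adjusted over the list alone. Camera with the correlation estimated from the data, and fry, which tests whether the genes of a list move on balance in a single direction without setting them against other genes, were run as alternatives. With the estimate, camera also takes its degrees of freedom from the libraries and not from the number of genes, which by itself raises p. Genes within 20 Mb of Thbs2 were compared with all other tested genes by Fisher's exact test.

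The rule for the genes named was fixed before the data were examined. Thbs2 was always named. Then came up to 10 genes with the largest fold change in each direction among those past the threshold, with a mean of at least 50 and no overlap between the groups. Predicted or unnamed loci and sex-linked genes were passed over. Where fewer than 5 genes passed in a direction, the 5 with the smallest unadjusted p were named as not past the threshold. From each list, up to 4 members with the smallest p could be named. Other genes are named as chosen after their values were seen.

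The test was tested on simulated data drawn for the same 14707 genes with their measured means and spreads, with 200 genes changed in each of 5 simulations. It recovered 12% of genes changed 2-fold, 56.8% of those changed 4-fold, 71.2% of those changed 8-fold and 80.4% of those changed 16-fold. Of the unchanged genes, 5.03% had an unadjusted p under 0.05, and 34 passed the threshold over the 5 simulations together. The simulated genes were drawn independently of each other, while the measured genes vary together across libraries. These rates therefore need not hold for the measured libraries.

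Settings chosen before the data were examined were pseudocounts of 0.1 and 10, no filter and a mean of at least 100, rescaling by trimmed means of log ratios (TMM, computed on the values), quantile normalisation, limma without the trend or with robust shrinkage, the replicate number as a block, each library left out in turn, and a window of 10 Mb around Thbs2. Chosen after seeing the data were limma-voom on the estimated reads, camera with an estimated correlation and each library left out, thinning of the estimated reads to the depth of the shallowest library, and a covariate holding the mean of the keratinocyte markers or of the G2 and M phase genes.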

Results

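Gene expression was compared between dermal fibroblasts of WT mice and of mice labelled TSP2KO, with 3 libraries each. Thrombospondin-2, encoded by Thbs2, is a matricellular glycoprotein, a secreted protein of the extracellular matrix that acts on cells more than it builds structure. The series concerns the steady state of skin fibroblasts, and the comparison asks which transcripts differ in cultured cells without the protein. Macrophage markers were lower in TSP2KO as a list, with a median log2 fold change of -2.57 (camera adjusted p = 2.63e-28). With an estimated correlation the camera adjusted p was 0.0107, and 0.126 when the library labelled WT 3 was left out. The list's mean log2 fold change was -2.50 with all libraries and -2.54 without that library. Contractile genes of myofibroblasts were higher as a list, with a median of 1.27 (camera adjusted p = 2.95e-12; adjusted p = 0.422 with an estimated correlation). Over all genes, 9 passed the threshold, all lower in TSP2KO. Thbs2 itself was low in the 3 TSP2KO libraries and also in the library labelled WT 3. Estimated depth was 24988148, 34599724 and 18266727 reads for WT 1, WT 2 and the library labelled WT 3, and 20153410, 20521919 and 14776468 reads for TSP2KO 1, TSP2KO 2 and TSP2KO 3. Xist was listed at 0 in all 6 libraries, while the Y-linked gene Ddx3y lay between 1525 and 3570 normalised reads, so the libraries carried the transcripts of male cells.

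Thbs2 (chromosome 17, 14665500 to 14694235, minus strand) was high in WT 1 and WT 2, with 122061 and 116720 normalised reads. It was low in TSP2KO 1, TSP2KO 2 and TSP2KO 3, with 5177, 6635 and 4891. The library labelled WT 3 had 8841, which went against its label: it lay 13.5-fold below the mean of WT 1 and WT 2 and 1.59-fold above the TSP2KO mean. Over the labelled groups, the mean was 82541 ± 63882 (SD, n = 3) in WT and 5568 ± 936 (SD, n = 3) in TSP2KO, a log2 fold change of -3.18 (SE 0.95) that did not pass the threshold (limma adjusted p = 0.318). Without the library labelled WT 3 it was -4.43 (SE 0.22, limma adjusted p = 0.00257). The labels do not describe the construct, and values per gene do not part deleted exons from those that may remain.

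**Figure D1:**
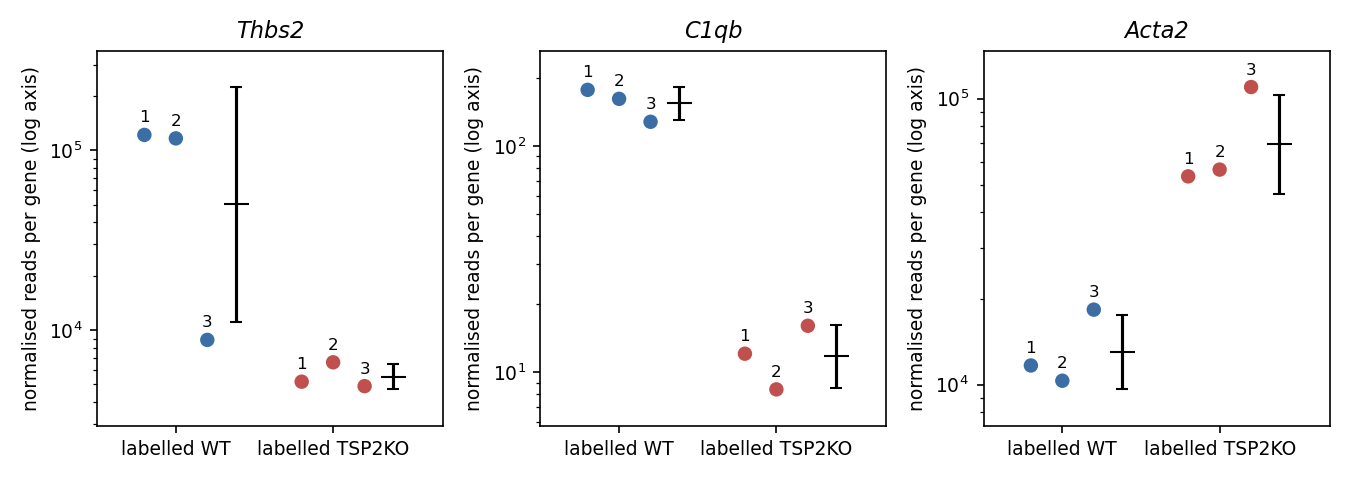
Normalised reads of Thbs2, C1qb and Acta2 in each library on log axes, with libraries numbered by replicate; the bar gives the mean and SD of the log2 values of the 3 libraries of each label. For Thbs2 the library labelled WT 3, at 8841, sits beside the TSP2KO libraries, whereas for C1qb and Acta2 it sits with WT 1 and WT 2.

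The library labelled WT 3 also stood apart from WT 1 and WT 2 over all tested genes. The first principal component, with 45.4% of the variance, placed WT 1 and WT 2 at -65.0 and -67.1 and the library labelled WT 3 at 64.1, beyond TSP2KO 1, TSP2KO 2 and TSP2KO 3 at 51.7, 20.5 and -4.05. The second component, with 33.8%, set TSP2KO 3 apart at -90.3. The log2 values of the library labelled WT 3 correlated across genes at 0.892 with both WT 1 and WT 2. With TSP2KO 1, TSP2KO 2 and TSP2KO 3 they correlated at 0.960, 0.939 and 0.880, the last below the values for WT 1 and WT 2. Genes are not independent replicates. Every direction below that uses the WT mean rests in part on this library.

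**Figure D2:**
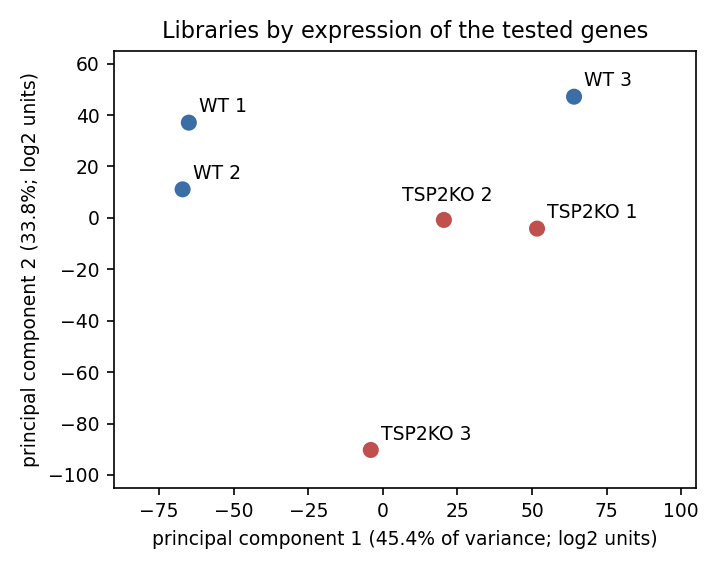
The 6 libraries on the first and second principal components of the log2 values of the tested genes, in log2 units, blue for libraries labelled WT and red for TSP2KO. WT 1 and WT 2 lie at -65.0 and -67.1 on the first component and the library labelled WT 3 lies at 64.1.

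Of 14707 genes tested, 9 passed the threshold, all lower in TSP2KO and all changed at least 2-fold. Of these 9, C1qb and Cd74 belong to the list of macrophage markers. Ccl6, a chemokine made largely by myeloid cells, had 193 ± 99.2 normalised reads in WT and 3.87 ± 1.94 in TSP2KO (SD, n = 3 each), 38.9-fold lower (log2 fold change -5.28, SE 0.52, limma adjusted p = 0.0456). C1qb, a chain of the complement component C1q that macrophages secrete, had 155 ± 25.1 in WT and 12.2 ± 3.82 in TSP2KO (log2 fold change -3.60, SE 0.33, adjusted p = 0.0456). Msr1, a macrophage scavenger receptor, had 94.6 ± 21.9 and 7.74 ± 1.66 (log2 fold change -3.44, SE 0.35). Lilrb4a, an inhibitory receptor of myeloid cells, had 230 ± 17.1 and 17.8 ± 6.64 (log2 fold change -3.67), and shares reads with a close paralog, so its value is uncertain. Slfn8, of the Schlafen family, fell from 172 ± 76.9 to 3.97 ± 1.54 (log2 fold change -5.05), with the same reserve over paralogs.

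Among the other 4 genes, Cyp7b1, an oxysterol hydroxylase, had 575 ± 279 normalised reads in WT and 44.0 ± 2.33 in TSP2KO (log2 fold change -3.57, SE 0.35, limma adjusted p = 0.0456). Il15ra, the alpha chain of the interleukin-15 receptor, had 889 ± 31.0 and 245 ± 50.6 (log2 fold change -1.87, SE 0.20, adjusted p = 0.0476). Cd53, a tetraspanin of leukocytes, and Cd74, the invariant chain of MHC class II, also passed, with log2 fold changes of -3.30 and -3.78; Cd53 fell outside the naming rule and was chosen after its values were seen. For each of the 9 genes the library labelled WT 3 lay above every TSP2KO library. The fit that called them held this library in WT, which favours such genes, so their position is no separate support. Without the library labelled WT 3 the 9 genes still passed, and the counts became 357 genes higher and 404 lower. Without any of the other 5 libraries, in turn, no gene passed in either direction.

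No gene passed as higher in TSP2KO by limma, although 538 were higher and 896 lower at an unadjusted p under 0.05. By limma-voom no gene passed in either direction, so the 9 lower genes were not called by it. Among the higher genes the limma results were as follows. The 5 with the smallest p were Ckb, Prss23os, Fhl1, Corin and Acta2. Ckb, the brain-type creatine kinase, had 330 ± 80.3 normalised reads in WT and 1063 ± 89.1 in TSP2KO (log2 fold change 1.71, SE 0.22, limma adjusted p = 0.0791). Corin, a membrane serine protease also known from the dermal papilla, had 25.0 ± 9.48 and 140 ± 24.8 (log2 fold change 2.49, SE 0.35, adjusted p = 0.0974). Prss23os, antisense to Prss23, had a log2 fold change of 2.22 and is uncertain, since the strand setting of the counting is not given. Without the library labelled WT 3 all 5 passed, with adjusted p between 0.00988 and 0.0225. Groups did not overlap for 2084 genes, 14.2% of those tested. Barring ties, 10% is the mean share over the 10 ways to part 6 libraries into 3 and 3. Genes vary together, so a single split can lie far from that mean, and the share does not show an effect of genotype.

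**Figure D3:**
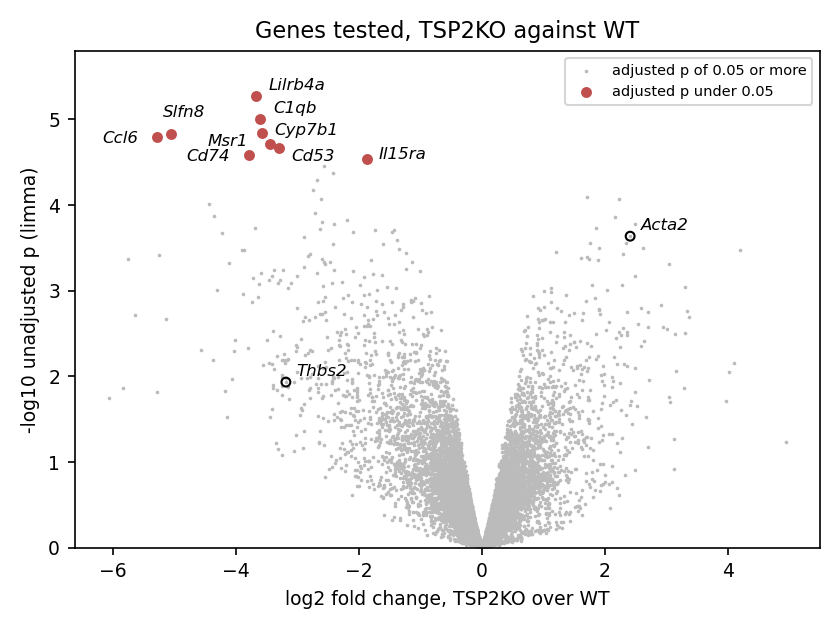
Log2 fold change of TSP2KO over WT against -log10 of the unadjusted limma p for the 14707 tested genes; red points are the 9 genes with an adjusted p under 0.05, and open circles mark Thbs2 and Acta2. All 9 red points lie on the side lower in TSP2KO, and Thbs2 lies at -3.18 with an adjusted p of 0.318.

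Macrophage and monocyte markers were lower in TSP2KO as a list. All 17 tested members were lower, with a median log2 fold change of -2.57 (camera adjusted p = 2.63e-28; adjusted p = 0.0107 with an estimated correlation). Past the threshold were 2 members over all genes and 16 adjusted over the list alone; without the library labelled WT 3, 13 passed over all genes. Lyz2, lysozyme and the most abundant of the members quoted, had 3334 ± 1433 normalised reads in WT and 479 ± 103 in TSP2KO (log2 fold change -2.71, SE 0.36, limma adjusted p = 0.0974); it was chosen after its values were seen. C1qc and Ctss, which encodes the lysosomal protease cathepsin S, had log2 fold changes of -2.67 and -2.74 (adjusted p = 0.0634 and 0.0750). Relative to the mean of WT 1 and WT 2, the list's mean log2 value was -0.11 in the library labelled WT 3 and -2.62, -2.45 and -2.55 in TSP2KO 1, TSP2KO 2 and TSP2KO 3. Of the 42 lists tested, 18 passed with the preset correlation and this list alone passed with an estimated correlation. The estimate was -0.0195 for this list, -0.0257 for hypoxia and glycolysis and -0.0382 for TGF-beta response genes, below the preset 0.01. For these lists the larger p with the estimate does not come from a higher correlation between genes. The other lists past the threshold had estimates above the preset, from 0.0126 for angiogenesis regulators to 0.958 for G2 and M phase genes. Interferon response genes had 0.718 and contractile genes 0.396. There the preset understates the estimated correlation, and its part in the larger p was not told apart from that of the degrees of freedom. With an estimated correlation the macrophage list did not pass without the library labelled WT 3 (adjusted p = 0.126), TSP2KO 1 (0.0523) or TSP2KO 2 (0.0559). It passed without each of the other 3 (up to 0.0456). Each library left out lowered the degrees of freedom, and the adjusted p rose in each case. The mean log2 fold change was -2.50 with all libraries and -2.54, -2.46 and -2.55 in the 3 fits that did not pass. The size of the difference hardly moved.

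Other immune lists were lower as well, in the same TSP2KO libraries in which macrophage markers lay at -2.62, -2.45 and -2.55. Interferon response genes had 30 of 31 members lower and a median log2 fold change of -1.58 (camera adjusted p = 1.12e-15; adjusted p = 0.482 with an estimated correlation), with 23 members past adjusted over the list alone and 0 over all genes (10 without the library labelled WT 3). Ifi44 and Oas1a, both induced by interferon, had log2 fold changes of -3.39 (SE 0.77) and -3.02 (SE 0.76) (limma adjusted p = 0.207 and 0.246). The list's mean log2 value was -1.16 in the library labelled WT 3, as in TSP2KO 2, against -2.54 and -2.83 in TSP2KO 1 and TSP2KO 3. Complement genes had a median of -1.54 (camera adjusted p = 1.29e-08; adjusted p = 0.139 with an estimated correlation), with 8 of 15 members past adjusted over the list alone and 0 over all genes (6 without the library labelled WT 3). Among them were C3, the central component of the cascade, at 301 ± 165 and 18.9 ± 9.50, and Serping1, the C1 inhibitor, at 8642 ± 3117 and 2463 ± 531. Antigen presentation genes had a median of -1.09 (camera adjusted p = 4.83e-08; adjusted p = 0.482 with an estimated correlation), with 7 of 16 past adjusted over the list alone and 1, Cd74, over all genes (2 without the library labelled WT 3), among the 7 B2m at 24867 ± 9552 and 11300 ± 1721. H2-Q6, another of the 7, shares reads with near-identical H2-Q genes and is uncertain.

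Inflammatory cytokines and chemokines were lower as a list, with a median log2 fold change of -1.51 (camera adjusted p = 6.32e-07; adjusted p = 0.482 with an estimated correlation) and 12 of 26 members past adjusted over the list alone. Cxcl12, a chemokine made by fibroblasts, had 13010 ± 2560 normalised reads in WT and 1830 ± 1121 in TSP2KO (log2 fold change -3.10, SE 0.56, limma adjusted p = 0.138). Il33, an alarmin, had 970 ± 580 and 79.8 ± 62.5, and its receptor gene Il1rl1 had 16266 ± 7652 and 4350 ± 1101. The list's mean log2 value in the library labelled WT 3 was 1.75 above the mean of WT 1 and WT 2, while macrophage markers there lay at -0.11. Without this library the list's mean log2 fold change was -1.12 in place of -1.71 (camera adjusted p = 0.0205; adjusted p = 0.588 with an estimated correlation), and 5 members were lower and 1 higher past the threshold over all genes, against 0 with it.

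Contractile genes were higher as a list. Of 20 myofibroblast and contractile genes, 16 were higher in TSP2KO, with a median log2 fold change of 1.27 (camera adjusted p = 2.95e-12; adjusted p = 0.422 with an estimated correlation). Past the threshold were 0 over all genes and 14 adjusted over the list alone, all higher; without the library labelled WT 3, 10 passed over all genes. Acta2, smooth muscle actin, the usual marker of myofibroblasts, had 13426 ± 4268 normalised reads in WT and 73290 ± 31704 in TSP2KO, 5.32-fold more (log2 fold change 2.41, SE 0.36, limma adjusted p = 0.101). Tagln, transgelin, had 2168 ± 747 and 14090 ± 7860 (log2 fold change 2.62), and Actg2, enteric smooth muscle actin, had 809 ± 425 and 9325 ± 8196 (log2 fold change 3.31). Fhl1, a LIM domain protein of muscle, had 881 ± 104 and 4158 ± 1795 (log2 fold change 2.16, SE 0.30, adjusted p = 0.0974). The library labelled WT 3 lay with WT 1 and WT 2 here, at 0.16 above their mean log2 value, against 0.99, 1.31 and 2.07 in TSP2KO 1, TSP2KO 2 and TSP2KO 3, where macrophage markers lay at -2.62, -2.45 and -2.55. TGF-beta response genes had a median of 0.40 (camera adjusted p = 0.0243; adjusted p = 0.422 with an estimated correlation; 0.0804 without the library labelled WT 3). Tgfb2 and Tgfb3 were higher and Tgfbi lower adjusted over the list alone, with log2 fold changes of 0.91, 1.22 and -2.55; 0 members passed over all genes, against 4 higher and 1 lower without that library.

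Growth and energy lists were higher, and here the library labelled WT 3 lay with TSP2KO. Keratinocyte markers were also high in this library, TSP2KO 1 and TSP2KO 2, at 4.78, 3.42 and 3.28 above the mean log2 value of WT 1 and WT 2, but not in TSP2KO 3, at -0.95. All 26 G2 and M phase genes were higher, with a median log2 fold change of 0.83 (camera adjusted p = 8.33e-06; adjusted p = 0.691 with an estimated correlation), and 0 passed adjusted over the list alone. Aurka, a mitotic kinase, had 205 and 221 normalised reads in WT 1 and WT 2, 1155 in the library labelled WT 3, and 981, 749 and 655 in TSP2KO 1, TSP2KO 2 and TSP2KO 3. Without the library labelled WT 3, 20 of the 26 passed over all genes, as did 11 of 24 S phase genes, 1 of 13 mitochondrially encoded genes and 1 of 6 skeletal muscle markers. S phase genes had a median of 0.49 (camera adjusted p = 0.000667), ribosomal proteins 0.33 (0.000267), mitochondrially encoded genes 0.69 (0.000395) and nuclear genes of the respiratory chain 0.20 (0.00426). The S phase, ribosomal, mitochondrially encoded and respiratory lists each had an adjusted p = 0.691 with an estimated correlation and 0 members past adjusted over the list alone. Without the library labelled WT 3 the mean log2 fold change was 1.57 in place of 0.84 for G2 and M phase genes, 1.11 in place of 0.58 for S phase genes, 0.58 in place of 0.33 for ribosomal proteins and 1.19 in place of 0.70 for mitochondrially encoded genes. Without WT 1 these means were 0.50, 0.30, 0.12 and 0.33, and without WT 2 they were 0.46 and 0.31 for the G2 and M phase and S phase genes. The S phase list ended without WT 1 or WT 2 (adjusted p up to 0.0628), the ribosomal list without WT 1 (0.0897) and the respiratory list without WT 2 (0.0537). Skeletal muscle markers, with 6 members tested, had a median of 0.92 (camera adjusted p = 0.0234; adjusted p = 0.689 with an estimated correlation). That list had 0 members past adjusted over the list alone and ended without WT 1, WT 2, TSP2KO 1 or TSP2KO 2 (adjusted p up to 0.0897); its mean of 1.24 was 0.72 without WT 1 and 2.13 without the library labelled WT 3. Acta1, skeletal muscle actin, led it, with 6.70 and 12.2 normalised reads in WT 1 and WT 2, 203 in the library labelled WT 3 and 464 ± 164 (SD, n = 3) in TSP2KO.

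The other lower lists had smaller medians, in libraries that also differed in macrophage markers (-2.57). Hypoxia and glycolysis genes had 22 of 24 members lower and a median log2 fold change of -0.27 (camera adjusted p = 0.000167; adjusted p = 0.139 with an estimated correlation), with 4 past adjusted over the list alone. Of the 4, Bnip3, a mitochondrial protein induced by hypoxia, had 1808 ± 395 normalised reads in WT and 661 ± 29.8 in TSP2KO (log2 fold change -1.43, SE 0.21, limma adjusted p = 0.0974). Schwann cell and neural crest markers had a median of -0.92 (camera adjusted p = 0.000395; adjusted p = 0.691 with an estimated correlation), with 3 of 22 past adjusted over the list alone and a mean of -0.86 that was -0.55 without TSP2KO 3. Gfap, an intermediate filament of glia, was among the 3 at 74.9 ± 38.8 and 2.95 ± 1.96. Matrix proteases and inhibitors had a median of -0.54 (camera adjusted p = 0.00119; adjusted p = 0.482 with an estimated correlation), with 6 lower and 1 higher of 31 past adjusted over the list alone. Mmp12, the macrophage elastase, had 350 ± 109 and 38.7 ± 26.2. Angiogenesis regulators had a median of -0.37 (camera adjusted p = 0.0214; adjusted p = 0.422 with an estimated correlation) and 1 of 28 past adjusted over the list alone; without the library labelled WT 3 the adjusted p was 0.304. Immediate early genes had a median of -0.34 (camera adjusted p = 0.0251; adjusted p = 0.691 with an estimated correlation) and 1 of 19 past adjusted over the list alone. That list ended without the library labelled WT 3 or without TSP2KO 3 (adjusted p up to 0.234). None of these 5 lists had a member past the threshold over all genes; without the library labelled WT 3, 2 hypoxia, 6 Schwann cell and 4 angiogenesis genes were lower past it, and 9 matrix proteases and inhibitors were lower and 2 higher. Without TSP2KO 3 the mean log2 fold change was -0.37 in place of -0.55 for angiogenesis regulators and -0.30 in place of -0.57 for immediate early genes.

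**Figure D4:**
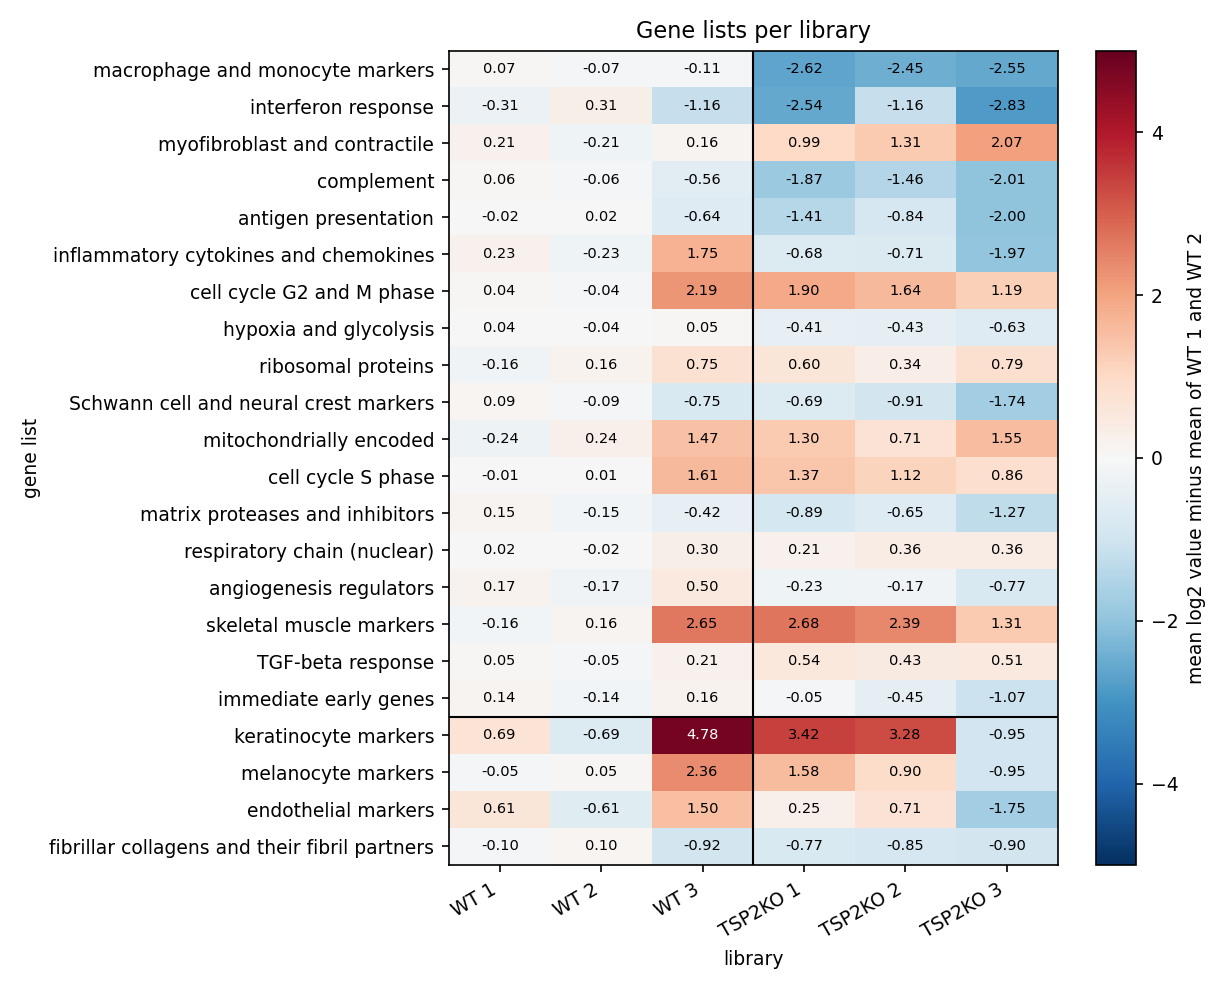
Mean log2 value of each list in each library, minus the mean of WT 1 and WT 2, for the 18 lists past the threshold (above the line) and 4 others; the colour bar gives log2 units. The library labelled WT 3 lies with WT 1 and WT 2 for macrophage markers, at -0.11, and with TSP2KO for G2 and M phase genes, at 2.19.

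Matrix genes did not pass as lists with all libraries. Fibrillar collagens and their partners had a median log2 fold change of -0.22 (camera adjusted p = 0.203), and 1 of 21 members, Dcn, passed adjusted over the list alone. The list passed as lower without the library labelled WT 3 (camera adjusted p = 0.0101; adjusted p = 0.477 with an estimated correlation) and without TSP2KO 3 (camera adjusted p = 0.00937; adjusted p = 0.757 with an estimated correlation). Its mean log2 value, relative to WT 1 and WT 2, was -0.92 in the library labelled WT 3 and -0.77, -0.85 and -0.90 in TSP2KO 1, TSP2KO 2 and TSP2KO 3. Dcn, decorin, had 48265 ± 8831 normalised reads in WT and 8554 ± 5386 in TSP2KO (log2 fold change -2.80, SE 0.61, limma adjusted p = 0.182). Matricellular proteins had a median of -0.49 (camera adjusted p = 0.240), with Tnc, tenascin-C, at 70190 ± 4924 and 19898 ± 8860; Tnc and Tgfbi were lower adjusted over the list alone. That list passed as lower without the library labelled WT 3 (camera adjusted p = 0.0323; adjusted p = 0.508 with an estimated correlation). Basement membrane genes (camera adjusted p = 0.464) went both ways, with Col15a1, Col4a1, Col7a1 and Nid2 higher and Lama4 lower adjusted over the list alone. Elastic fibre and crosslinking genes (0.561) and integrins and adhesion genes (0.716) did not pass; in the integrin list, Itga8 was higher adjusted over the list alone, at 706 ± 275 and 2289 ± 76.0.

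Markers of several other cell types did not pass as lists by genotype with all libraries. The camera adjusted p was 0.192 for melanocyte, 0.225 for endothelial, 0.534 for lymphocyte and mast cell, 0.540 for keratinocyte, 0.178 for pericyte and smooth muscle and 0.561 for chondrocyte and osteoblast markers. Without the library labelled WT 3, keratinocyte markers (camera adjusted p = 0.0101) and pericyte and smooth muscle markers (0.0448) passed as higher, with adjusted p = 0.718 and 0.477 with an estimated correlation. Keratinocyte markers also passed as higher without TSP2KO 3 (camera adjusted p = 0.00101; adjusted p = 0.757 with an estimated correlation). Endothelial markers passed as lower without WT 2 (0.00175) or TSP2KO 2 (0.0148), with adjusted p = 0.803 and 0.786 with an estimated correlation, and melanocyte markers without TSP2KO 1 (0.0497), with adjusted p = 0.619 with an estimated correlation. In the lymphocyte and mast cell list, with 5 members tested, Gzmb and Cd28 were lower and Trac higher adjusted over the list alone. Gzmb, a cytotoxic protease, had 1134 and 191 normalised reads in WT 1 and WT 2, 3.85 in the library labelled WT 3 and 0.942 ± 0.858 in TSP2KO (limma adjusted p = 0.333). Lyve1, a receptor of lymphatic endothelium and of some macrophages, had 195 ± 73.8 normalised reads in WT and 5.42 ± 7.95 in TSP2KO (log2 fold change -5.75, SE 0.94, limma adjusted p = 0.111) and passed adjusted over the list alone. Fibroblast subtypes did not pass either, with 0.141 for dermal papilla and sheath, 0.687 for papillary genes and 0.687 for reticular, fascia and universal genes. The dermal papilla list passed as higher without the library labelled WT 3 (0.0205) or TSP2KO 3 (0.0117), with adjusted p = 0.517 and 0.726 with an estimated correlation.

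The remaining lists did not pass with all libraries. The camera adjusted p was 0.134 for YAP and TEAD targets, 0.168 for p53 targets and senescence, 0.305 for NRF2 and oxidative stress, 0.540 for growth factors and receptors of fibroblasts, 0.541 for the unfolded protein and ATF4 response, 0.541 for adipogenic and lipid genes, 0.541 for the Wnt pathway and 0.541 for cholesterol synthesis. It was 0.630 for histones whose RNA is poorly polyadenylated and 0.992 for Hox genes. The YAP and TEAD list (0.0331) and the cholesterol list (0.0119) passed without WT 1, and the p53 list (0.0484) without TSP2KO 1, with adjusted p = 0.512, 0.521 and 0.565 with an estimated correlation. In the growth factor list, Igfbp2, which binds insulin-like growth factors, had 16.3 ± 4.48 normalised reads in WT and 160 ± 94.7 in TSP2KO, and Pdgfra, a receptor that marks fibroblasts, had 16929 ± 4007 and 6249 ± 2039. Both passed adjusted over the list alone, and neither passed over all genes (limma adjusted p = 0.113 and 0.162). The median, mean and test differed in sign for the growth factor, histone, papillary, integrin and Hox lists.

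Genes near Thbs2 were examined because DNA beside a targeted allele can come from another mouse strain. Of 351 tested genes within 20 Mb on chromosome 17, 0 passed by limma, against 9 of 14355 other genes (Fisher's exact test, two-sided, p = 1). Without the library labelled WT 3, 18 of the 351 passed, 5.13%, against 742 of 14355 others, 5.17%.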

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

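Limma-voom, thinning, the covariates and the estimated correlation with a library left out were chosen after seeing the data, while the other alternatives were planned. The planned edgeR and DESeq2 tests were not run, since whole reads were not recovered. The count of 9 lower genes, all changed at least 2-fold, became 0 with a pseudocount of 0.1, without a filter, with a mean of at least 100, with quantile normalisation, with limma-voom and with the replicate number as a block. The smallest adjusted p was then 0.0529, 0.0845, 0.116, 0.0554, 0.109 and 0.0907. With a mean of at least 100, 3 of the 9 genes were still tested and did not pass. The others of the 9 had means below that filter and were not tested there. Why the tested genes no longer passed was not examined. The count was 14 with a pseudocount of 10, 15 without the trend, 7 with TMM rescaling, 9 with robust shrinkage, 9 after thinning and 10 with the G2 and M phase covariate. Of the 9 genes, 9, 8, 7, 9, 8 and 5 were among those. With the keratinocyte covariate 36 genes were lower and 3 higher (Ckb, Fhl1 and Prss23os), 39 in all at least 2-fold, and the 9 were kept. Leaving out each library in turn gave 0 to 357 genes higher, 0 to 404 lower and 0 to 688 at least 2-fold; the upper values come from the fit without the library labelled WT 3, and the other 5 fits gave 0.

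The Thbs2 log2 fold change kept its sign under every alternative run and ranged from -2.54 to -4.43 over the libraries left out, passing the threshold in the fit without the library labelled WT 3 alone (adjusted p = 0.00257, against 0.149 to 0.814 elsewhere). It was -1.86 with the G2 and M phase covariate. The 18 lists became 1 with an estimated correlation and 4 with fry, and 16 to 20 when each library was left out. Of the 18, 11 passed in each of those 6 fits. The 4 with fry were the macrophage, hypoxia, TGF-beta and complement lists (fry adjusted p = 0.000153, 0.0171, 0.0194 and 0.0283). The contractile, interferon and cytokine lists were among those that did not pass with fry (fry adjusted p = 0.110, 0.242 and 0.309). The cell cycle lists were not followed under the G2 and M phase covariate. It fixes the G2 and M phase list by construction. The S phase list is not part of the covariate but was left out with it. Of the other 16, the mitochondrially encoded, respiratory, ribosomal and skeletal muscle lists did not pass under it (adjusted p = 0.201, 0.151, 0.287 and 0.419), although 18 lists passed in all. The skeletal muscle list also did not pass without a filter (0.288; 17 lists passed), with a mean of at least 100 (0.0623; 16 lists) and after thinning (0.116; 17 lists), and the TGF-beta list did not with a mean of at least 100 (0.0977). Genes near Thbs2 numbered 1 without the trend (Myo1f, log2 fold change -2.59, chosen after its values were seen), and 0 to 18 over the libraries left out. Of the 79 named genes and list members followed, 1 changed sign: Chrna1, at -0.15 with the G2 and M phase covariate; the cause was not tested.

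The replicate numbers did not pair the libraries: deviations of same-numbered libraries from their group means correlated at -0.42, -0.25 and -0.39, and no WT library correlated best with its own number. Depth limits the low genes most, since a read is worth 0.392 to 0.890 normalised units; after thinning to 14776468 reads 9 genes passed the threshold, 8 of them among the 9 at full depth.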

Other observations

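The tests of the library labelled WT 3, of the macrophage and interferon genes and of the keratinocyte markers were chosen after the results were seen, as were the splits for genes changed at least 2-fold and for lists, and the fit used near Thbs2. Some skin genes also varied within a genotype. Krt14, a keratin of basal keratinocytes, had 553 and 180 normalised reads in WT 1 and WT 2, 15525 in the library labelled WT 3, 5061 and 4727 in TSP2KO 1 and TSP2KO 2 and 157 in TSP2KO 3. Wif1, a Wnt inhibitor of the dermal papilla, had 87.4 ± 125 in WT and 324 ± 58.6 in TSP2KO (SD, n = 3 each; limma adjusted p = 0.362), with 232 in the library labelled WT 3. Krt14 was chosen after its values were seen.

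The library labelled WT 3 lay near TSP2KO on Thbs2 and for most genes that separate WT 1 and WT 2 from TSP2KO. Of 761 genes past the threshold without it, it lay nearer the TSP2KO mean for 76.5%, but the 13 macrophage markers among them had a median position of 0.112, with 0 at WT 1 and WT 2 and 1 at TSP2KO. A swap with a TSP2KO library was argued against, since the highest TSP2KO value of Thbs2 was 5.68% of the lower of WT 1 and WT 2. A wrong label of this library alone stays open: its Thbs2 log2 value lay 0.585 half-widths of the 95% prediction interval above the TSP2KO mean, while its macrophage genes did not follow. Relative to WT 1 and WT 2, its contractile genes lay at 0.16, against 0.99, 1.31 and 2.07 in the TSP2KO libraries. Its cytokine genes lay at 1.75, against -0.68, -0.71 and -1.97. Other lists lay with TSP2KO, such as G2 and M phase genes at 2.19, against 1.90, 1.64 and 1.19. A different growth state of the cultures stays open too: the G2 and M phase score of this library lay 1.39 of the way from WT 1 and WT 2 to TSP2KO, but that score is part of the pattern and decides nothing.

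Macrophage markers were lower in TSP2KO, including against the library labelled WT 3. A lower share of macrophages in the TSP2KO cultures and a change within macrophages cannot be told apart here: 94.1% of the 17 markers were lower in every TSP2KO library than in every WT library, which either would give. The culture step was meant to enrich fibroblasts, and no sort is described. Whether the same share accounts for the interferon genes cannot be told apart here: the interferon list differed between the library labelled WT 3 and TSP2KO 2 by -0.0043 in log2 units, where the macrophage list differed by 2.34, but by 1.38 and 1.67 against TSP2KO 1 and TSP2KO 3. An effect of the genotype stays open as well, untested.

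Keratinocyte markers were high in the library labelled WT 3, TSP2KO 1 and TSP2KO 2, across genotypes. Of the 17 markers, 15, or 88.2%, were higher in each of these libraries than in each of the others, which restates the pattern, so carry-over of epidermal cells stays open without a test that could decide it. A difference in depth was argued against: the log2 difference was 4.14 at full depth and 4.19 after thinning to the same depth. Because the pattern crosses the groups, no biological explanation was tested.

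Of the 10 ways to part the 6 libraries into 3 and 3, the labelled one gave 9 genes, 9 genes at least 2-fold and 18 lists, and the highest of the others gave 3, 3 and 16; in each case 1 of the 10 was as large. The smallest p that 10 splits allow is 0.1, so no share under 0.05 could be reached. The split with 3 genes set WT 1, WT 2 and TSP2KO 3 against the rest, which follows the keratinocyte markers. It had 2050 genes at an unadjusted p under 0.05. Another, WT 1, WT 2 and TSP2KO 2 against the rest, had 2963 genes at an unadjusted p under 0.05 against 1434 for the labels, which points to a structure of the libraries beyond the labels.

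The comparison near Thbs2 called no gene over all libraries, so the fit without the library labelled WT 3 was then used. Its odds ratio was 0.992, with a 95% interval from 0.577 to 1.60 (Fisher's exact test, p = 1), which leaves a modest excess of flanking genes open. Within 10 Mb, 10 of 149 genes passed in that fit, 6.71%, against 5.15% of the others. The odds ratio was then 1.32, with a 95% interval from 0.619 to 2.52 (Fisher's exact test, p = 0.352).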
